A study of Homo sapiens with 27 samples.

How the data were processed

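The series holds 27 arrays with 2 channels each, made from human CD4 T cell lines that had been grown for a short time from blood mononuclear cells. Per the labels, the lines came from lupus patients or normal subjects, rested for 10 days, and were then given plate-bound anti-CD3 with no second signal for 1 to 20 h. They then rested for 3 days and received anti-CD3 again for 3 or 6 h. The labels define 3 arms of 9 arrays. LN arrays set lupus cells against normal cells, NN arrays set cells of normal subjects against each other, and N328 arrays set normal cells given anti-CD3 alone against normal cells given anti-CD3 with anti-CD28. Each arm has 1 array per time point, so arrays of an arm at different times stood in for replicates. Nothing in the labels says whether these arrays came from separate cultures or donors. P-values therefore measure only a spread between arrays, in most fits that within the first stimulation. Part of it is change over time and part may be technical.

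The deposited values are log10 ratios of the 2 channels of an array, as read from the values themselves, since the unit is not given in the sources used here. Of 10910 values that occur repeatedly, 33.2% were simple fractions when read as log10, 0.13% when read as log2 and 0.43% when read as natural logs (denominators up to 60, tolerance 1e-06). A total of 79.9% of the deposited ratios were ratios of whole numbers with a denominator under 2000, against 0.32% of random values of the same spread. The scanner, the dyes, the background correction and the normalization are not given in the sources used here, and array medians lay between -0.14 and 0.10 on the log2 scale. All values were turned to log2 and each array was centred on its median. With no scanner signals at hand, depth could not be given, and the number of arrays limits the precision.

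Dyes are not stated. Signed values are given as likely lupus over normal on LN arrays, because the labels name lupus cells first and as the first channel, and as likely anti-CD3 alone over anti-CD3 with anti-CD28 on N328 arrays, from the order of the label. The sign of an NN ratio has no biological meaning. No 2 of the 9 arrays used in the tests correlated below -0.21 over all genes and probes, and the 6 LN arrays correlated with each other at 0.06 to 0.49 (Pearson's r across genes, which are not independent replicates).

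Probe names came from the platform annotation, of which 7432 probes had 1 gene symbol, 252 had several and 1498 of 9182 had none. Symbols were matched through gene identifiers to current RefSeq names for 7412 probes, and no symbol changed. Probes of 1 symbol were averaged per array (587 of 6798 genes had more than 1 probe). Probes with several symbols or none were tested but not named, which gave 8548 genes and probes. No genome build is named for the annotation used here, so no coordinates are printed.

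The columns of the value table turned out not to share 1 row order. The whole numbers behind a ratio give a proxy for spot brightness, and this proxy should correlate between arrays of 1 design when their rows match. It did so for 10 arrays (Spearman's rho 0.48 to 0.73), on which probes of the same gene also resembled each other over 661 pairs of probes (rho 0.06 to 0.36). That second relation passed for 9 of the 10 arrays in a permutation test with 2000 shuffles (the exception was the N328 array at 20 h, adjusted p = 0.164). A further 7 arrays shared another order (rho 0.42 to 0.61), and 10 matched no other array. Brightness correlated between arrays of different orders at -0.02 to 0.05. Of the 17 arrays outside the annotation order, 16 did not pass that test (adjusted p of 0.148 or more), and the exception was the NN array at 3 h (rho 0.10, adjusted p = 0.0229). Shifting or reversing rows did not align these 17 arrays (largest correlation 0.05, against 0.80 for a control array shifted on purpose). Shuffling the rows of the 10 arrays as a check lowered their median correlation from at least 0.53 to at most 0.03 in size. The cause of the different orders is not given in the sources used here.

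Genes were therefore read from the 10 arrays in annotation order alone: 6 LN arrays, 1 NN array and 3 N328 arrays. The LN arrays were those at the first rest, at 1, 3 and 6 h of the first stimulation, at the second rest and at 3 h of the second stimulation. The NN array was that at 1 h of the first stimulation, and the N328 arrays were those at 6 and 20 h of the first stimulation and 1 titled with both rests. This set was chosen after the data had been seen and departs from the plan, which used 26 arrays. The plan's contrasts were also computed over 8884 rows with every row taken as a probe. They called 16 rows for LN against NN over all times, 0 in the first stimulation, 0 in the second, 43 at rest, 0 for the change between stimulations and 0 for the time trend. N328 against NN gave 0 and 3 rows in the first and second stimulation, NN against 0 gave 0 and LN against 0 gave 332. Since rows of different arrays there belong to different probes, none of these counts was read as a result on genes. Unadjusted p fell under 0.05 for 570, 789, 630, 376, 145 and 839 rows in the contrasts with 0 calls, in the order just given.

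Tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on log2 ratios from 9 arrays, those in annotation order other than the one titled with both rests, with 1 coefficient per arm and stage. The spread rested on 3 residual degrees of freedom, from the 3 LN arrays and 2 N328 arrays of the first stimulation, and 6.02 prior degrees of freedom. Every other arm and stage held 1 array and is assumed to vary like those groups, the rests and the second stimulation included. Differences between rest, first and second stimulation do not enter this spread. The standard error of a mean over the 6 LN arrays therefore leaves them out. When either N328 array was left out, the other added nothing to the spread. In contrasts that hold no N328 array both omissions therefore gave the same result. Adjusted p is the Benjamini-Hochberg value over all genes and probes, with a threshold of 0.05. A total of 11 contrasts were fitted. The contrasts of LN against 0, NN against 0 (on the 1 NN array in annotation order), LN against NN over all times and in the first stimulation, and N328 against NN in the first stimulation were planned. Stimulated against resting LN arrays, second against first stimulation of LN arrays, resting LN arrays against 0, and LN arrays against the 3 arrays without lupus cells (a model of 2 groups with 7 residual degrees of freedom) were added after the data had been seen, and first-stimulation ratios of LN and N328 arrays against 0 were alternatives written down in advance. Models with and without stage terms and several scalings were looked at before the report was settled, and the model kept is the one planned.

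Gene lists were tested with camera from limma at a preset correlation between genes of 0.01 and again with an estimated one, adjusted over the lists of a contrast. Of 26 lists, 24 had at least 5 members on the array. Th1 genes and regulatory T cell genes had 4 members each and were not tested. The arrays of a contrast that stood alone were described with the percentile of a list's median among 10000 random lists matched on brightness in 20 bins.

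Before the data were examined, the gene lists, the fixed genes, the alternatives and the rule for named genes were written down. The rule took up to 10 genes with the largest change per direction among those past the threshold that lay on 1 side at every matched time point, or the 5 with the smallest p where fewer than 5 passed, the 4 members with the smallest p of each list, and a set of fixed genes in every contrast. Its extension to LN against 0 (the same sign on all 6 arrays) and to the added contrasts was made afterwards, as was the choice to print all 10 named genes called in NN against 0. Alternatives were no centring, scaling by the median absolute deviation (MAD), quantile normalization, single probes, robust eBayes, array weights, arm means, ratios against 0, and each array left out in turn. Leaving out the 25% of probes with the dimmest spots (2293), fitting all 26 arrays and turning the sign of the NN array in the 4 contrasts that hold it were added later.

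The tests were tried on simulated data, with 200 changed genes among 8548 in each of 5 runs. These were independent normal values whose variances came from the fits to the real arrays. They held no differences between stages and no correlation between arrays or genes, so they give no error rates for the real data. For LN against 0, 99.8% of genes changed by 1 on the log2 scale were recovered with each gene's own fitted variance, and 8.01% of the calls were false. With variances drawn from the fitted prior, 100% were recovered and 4.67% of calls were false. For LN against NN over all times, 81.2% and 50.8% were recovered, for the first stimulation 71% and 39.4%, and for N328 against NN 63.6% and 30%. Recovery was 97% and 79.4% for stimulated against resting LN arrays, and 98.6% and 95.8% for LN arrays against those without lupus cells. In the simulation for LN against 0, camera found 24 of 24 lists shifted by 0.3 and called 0 others. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the table and drew the plots.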

Results

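Gene expression ratios were measured on 27 arrays with 2 channels, 9 in each of 3 arms. The lupus/normal (LN) arrays compared T cell lines of lupus patients and normal subjects, the normal/normal (NN) arrays compared lines of normal subjects, and the N328 arrays compared normal cells given anti-CD3 alone with normal cells given anti-CD3 and anti-CD28. Anti-CD3 engages the T cell receptor, and anti-CD28 supplies the costimulatory signal whose absence induces anergy, a state of poor response to later stimulation. The number of values per array ranged from 6658 to 9182, and each arm had 1 array per time point.

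Of the 27 columns of ratios, 10 followed the row order of the probe annotation, 7 shared another order and 10 shared no order with any other column. Genes could be read on 6 LN arrays (first rest, 1, 3 and 6 h of the first stimulation, second rest, and 3 h of the second stimulation), on 1 NN array (1 h) and on 3 N328 arrays (6 h, 20 h and the array titled with both rests). All values below are log2 ratios or differences of log2 ratios, with their standard error, and are likely lupus over normal or anti-CD3 alone over anti-CD3 with anti-CD28, from the order of the labels, since dyes were not stated.

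**Figure D1:**
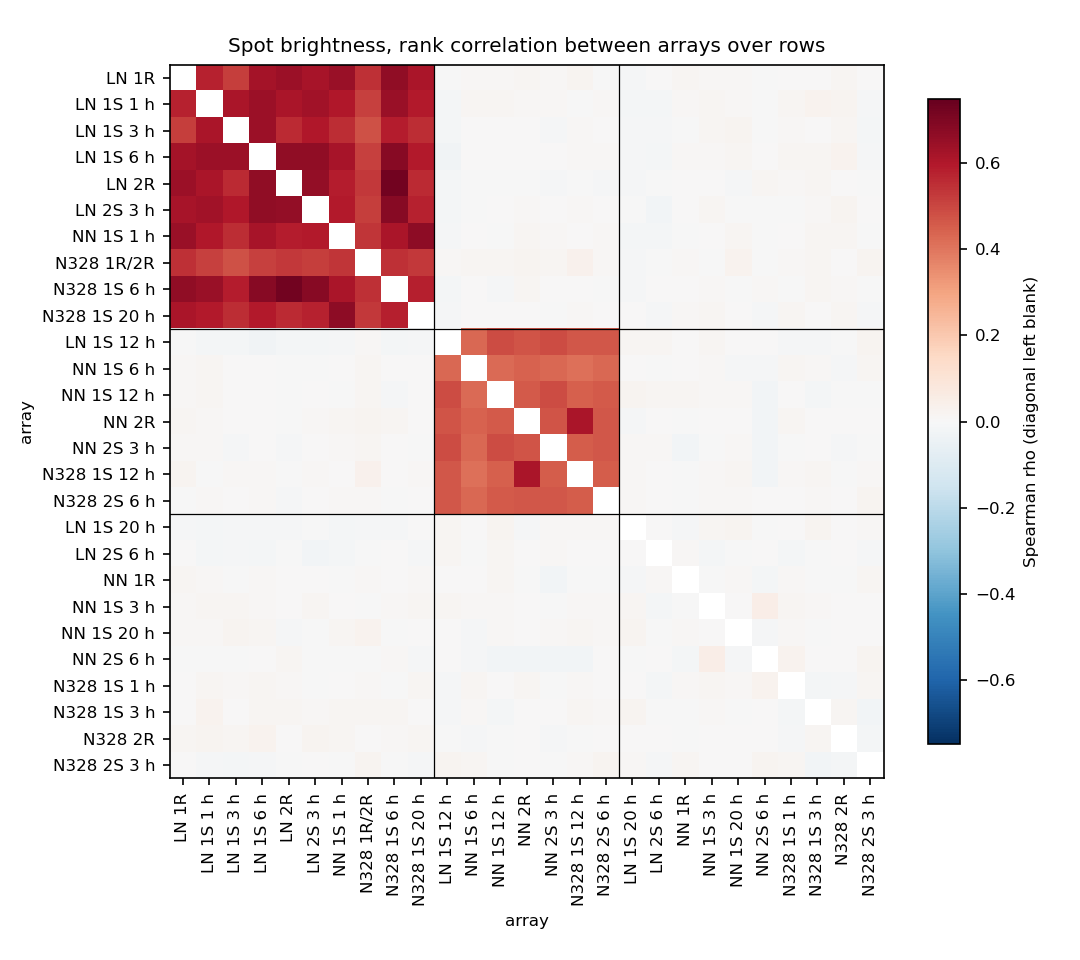
Spearman's rho of spot brightness between each pair of the 27 arrays over the rows of the table, with arrays on both axes ordered by row order and black lines between the 3 sets. The first block of 10 arrays lies between 0.48 and 0.73, the second block of 7 between 0.42 and 0.61, and all other pairs between -0.02 and 0.05.

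The first comparison asked which genes differed between lupus and normal lines over the 6 LN arrays. The standard errors of these means leave out the differences between rest, first and second stimulation. PTGS2, the gene of the prostaglandin-forming enzyme COX-2, was higher by 2.69 ± 0.16 (adjusted p = 0.000143, limma; positive on 5 of 6 arrays), and the neutrophil-attracting chemokine CXCL8 by 2.59 ± 0.26 (adjusted p = 0.00149; 6 of 6). Genes of the Th2 programme rose with them, IL13 by 1.57 ± 0.17 and its transcription factor GATA3 by 1.31 ± 0.16. The largest falls were those of IL7R, the receptor for the survival cytokine IL-7, at -1.41 ± 0.09 (adjusted p = 0.000143; 0 of 6 positive), and of CCR7, which directs T cells to lymph nodes, at -1.12 ± 0.10. In all, limma called 296 of 8548 genes and probes, 158 higher and 138 lower, of which 249 were named genes. Of the 296, 183 had 1 sign on all 6 arrays and 93 on 5. Every probe of PTGS2 was among the 25% with the dimmest spots by the brightness proxy. Leaving those probes out therefore gave PTGS2 no value.

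Further genes among the 10 largest rises with 1 sign on all 6 arrays were TSPAN13 (1.56 ± 0.19), the semaphorin and VEGF co-receptor NRP1 (1.48 ± 0.10), CSF2RB, the shared receptor chain for IL-3, IL-5 and GM-CSF (1.25 ± 0.15), the TGF-beta co-receptor TGFBR3 (1.21 ± 0.13), monoamine oxidase MAOA (1.19 ± 0.16), PHTF2 (1.18 ± 0.11) and the cytokine LIF (1.16 ± 0.08). Further falls were IL6ST, the signalling chain of the IL-6 receptor family (-0.97 ± 0.14), PATJ (-0.82 ± 0.09), NELL2 (-0.81 ± 0.09), PCGF3 (-0.75 ± 0.14), H2AC8 (-0.71 ± 0.10), the glucocorticoid receptor co-chaperone FKBP5 (-0.70 ± 0.12), ABLIM1 (-0.66 ± 0.08) and RPS29 (-0.65 ± 0.09). Adjusted p (limma) ranged from 0.000143 for NRP1, LIF and IL7R to 0.0266 for PCGF3. NRP1, like PTGS2, lay on dim probes alone, and NELL2 lay at percentile 3.57 of all genes and probes in spot brightness.

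**Figure D2:**
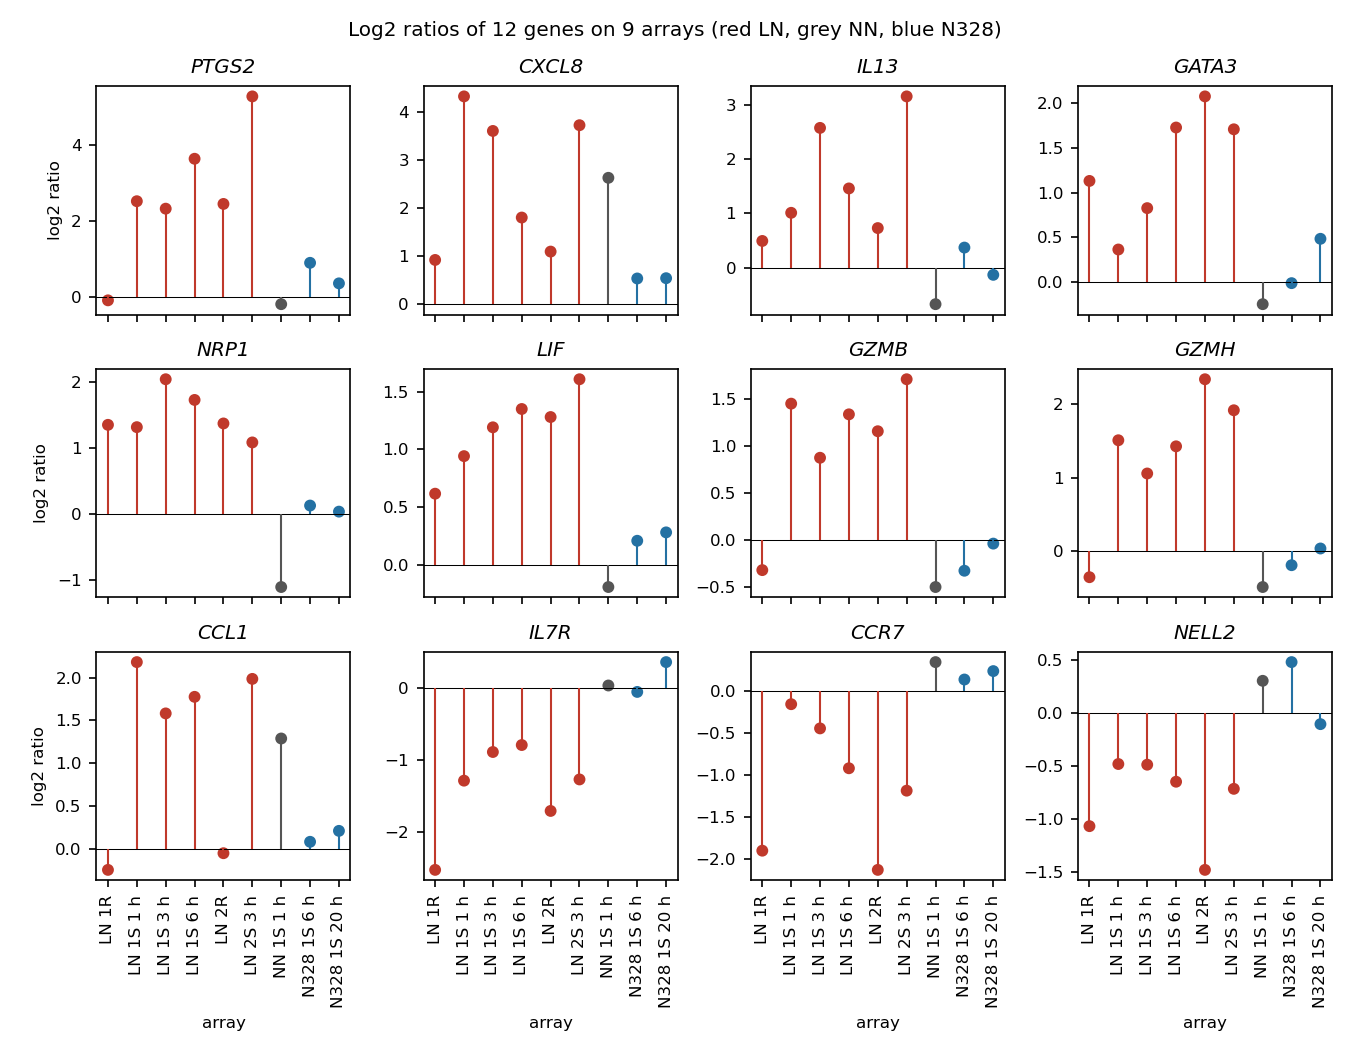
Log2 ratios of 12 genes on the 9 arrays used in the tests, 1 panel per gene with the array on the horizontal axis and the log2 ratio on the vertical axis, on a scale that differs between panels (red, LN; grey, NN; blue, N328). PTGS2 lies at -0.08 on the LN array at the first rest and between 2.33 and 5.28 on the other LN arrays, while IL7R lies between -2.52 and -0.79 on all 6.

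The NN array at 1 h, which compared normal lines, gave a scale for these ratios. Its direction has no meaning, so only the size of its values counts. On it CXCL8 stood at 2.64 and the chemokine CCL1 at 1.29, sizes within the range of the LN arrays. PTGS2 stood at -0.18, IL13 at -0.67, NRP1 at -1.11, IL7R at 0.03 and CCR7 at 0.35. On the N328 arrays at 6 and 20 h, PTGS2 stood at 0.91 and 0.37 and CXCL8 at 0.54 and 0.54. Tested against 0 with the spread of the other groups, the NN array gave 13 calls, 5 positive and 8 negative (limma; 546 at an unadjusted p under 0.05). The 10 named genes among them were RGS16 (2.08 ± 0.16, adjusted p = 0.00349), HOXD9 (1.29 ± 0.17), H2AX (-1.46 ± 0.16), the heat shock genes HSPA1A (-2.90 ± 0.35) and HSPA6 (-1.51 ± 0.22), the mitotic genes AURKA (-1.31 ± 0.18), CENPE (-1.60 ± 0.22) and CENPF (-1.26 ± 0.18), ENAH (-1.35 ± 0.19) and PRKACB (-1.44 ± 0.21). The count was 0 without the LN array at 3 h, 30 and 51 without those at 1 and 6 h, 8 without either N328 array, 51 with MAD scaling, 2 with quantile normalization, 24 with array weights, 8 with arm means and 7 without dim probes.

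Gene lists fixed in advance were tested on the same ratios with limma's camera, which called 9 of 24 lists, 6 up and 3 down, and 0 with an estimated correlation. Th2 genes rose as a group (adjusted p = 0.00113; adjusted p = 0.411 with an estimated correlation), with 2 of 7 measured members called over all genes and 3 when adjusted over the list alone, IL4 standing at 0.30 ± 0.08 (adjusted p = 0.0847). T cell cytokines rose (adjusted p = 0.0032; adjusted p = 0.411 with an estimated correlation), although their median of 0.07 in the LN mean lay at percentile 80.8 of random lists matched on brightness, with 4 of 13 called and 5 adjusted over the list alone. Among them were the macrophage growth factor CSF1 (1.06 ± 0.10) and TNFSF11, the ligand RANKL (0.33 ± 0.07). Activation and costimulation markers rose (adjusted p = 0.00121; adjusted p = 0.411 with an estimated correlation), with 4 of 19 called and 7 adjusted over the list alone. These were IL2RB (0.69 ± 0.08), CD58 (0.62 ± 0.11), TNFRSF8 (0.62 ± 0.11) and SLAMF1 (0.46 ± 0.09). Without the second stimulation TNFSF11, CD58, TNFRSF8 and SLAMF1 lost their calls (adjusted p 0.057, 0.0795, 0.0959 and 0.0795). TNFSF11 and SLAMF1 did so without 5 and 6 of the 9 arrays, each left out alone.

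Cytotoxic granule genes rose (adjusted p = 0.022; adjusted p = 0.411 with an estimated correlation), and 4 of 18 members were called, 5 higher and 1 lower when adjusted over the list alone. The granzymes GZMH (1.32 ± 0.08) and GZMB (1.03 ± 0.09) and SRGN, which packs granule proteases (0.57 ± 0.09), were called under every alternative. GZMA (0.73 ± 0.15) was not called under 7 of 17, and it fell to 0.30 without the second rest (adjusted p = 0.359) and 0.50 without the second stimulation (adjusted p = 0.158). Anergy-associated genes also rose as a list (adjusted p = 0.0261; adjusted p = 0.411 with an estimated correlation), with 3 of 17 members called higher and 1 lower, the same numbers when adjusted over the list alone. The 3 were NRP1, the transcriptional repressor CREM (0.81 ± 0.09) and NT5E, which makes adenosine (0.43 ± 0.09), and the 1 that fell was CBLB, a ubiquitin ligase needed for anergy (-0.30 ± 0.07, adjusted p = 0.047). NT5E and CBLB were not called under 9 and 10 of 16 alternatives, with the highest adjusted p (limma), 0.152 and 0.159, without the LN array at 3 h. NRP1, NT5E and CBLB lay on dim probes alone, so leaving those out gave them no value. Proteasome genes rose as a group (adjusted p = 0.018; adjusted p = 0.85 with an estimated correlation), with 0 of 29 members called in either way. Their median of 0.08 in the LN mean lay at percentile 95.5 of random lists matched on brightness, inside the central 95% of those lists.

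Ribosomal protein genes fell as a group (adjusted p = 1.59e-12, camera; adjusted p = 0.462 with an estimated correlation), with a median of -0.31 over 39 members. Of these, 8 were called over all genes and 20 when adjusted over the list alone, with RPS29, RPS3A (-0.55 ± 0.11), RPL37 (-0.48 ± 0.09) and RPL12 (-0.39 ± 0.08) among them. The latter 3 lost their calls without the second stimulation (adjusted p 0.0881, 0.121 and 0.12). The list median was negative on 5 of the LN arrays and 0.14 on the array at 3 h, and 0.23 in size on the NN array. Cell cycle genes fell in the LN mean, though not on every LN array (adjusted p = 0.00121; adjusted p = 0.411 with an estimated correlation), with 6 of 53 members called lower and 1 higher, 10 and 1 when adjusted over the list alone. The chromosome-segregation genes CENPA (-0.42 ± 0.07), TOP2A (-0.46 ± 0.09) and AURKB (-0.37 ± 0.08) fell, while the G1 cyclin CCND2 rose (0.82 ± 0.09). Without the first rest CENPA, TOP2A and AURKB lost their calls (adjusted p 0.0553, 0.118 and 0.198), AURKB standing at -0.23. Glycolysis genes fell (median -0.19, camera adjusted p = 0.00113, and adjusted p = 0.411 with an estimated correlation). PDK1, the kinase that inhibits pyruvate dehydrogenase, was called (-0.53 ± 0.09), and 6 of 15 were lower when adjusted over the list alone. Of the 9 called lists only T cell cytokines and proteasome genes had a median within the central 95% of random lists matched on brightness, while 2 lists that camera did not call lay outside it (COX-2 and eicosanoid genes at percentile 99.9 and NF-kB genes at 1.65).

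**Figure D3:**
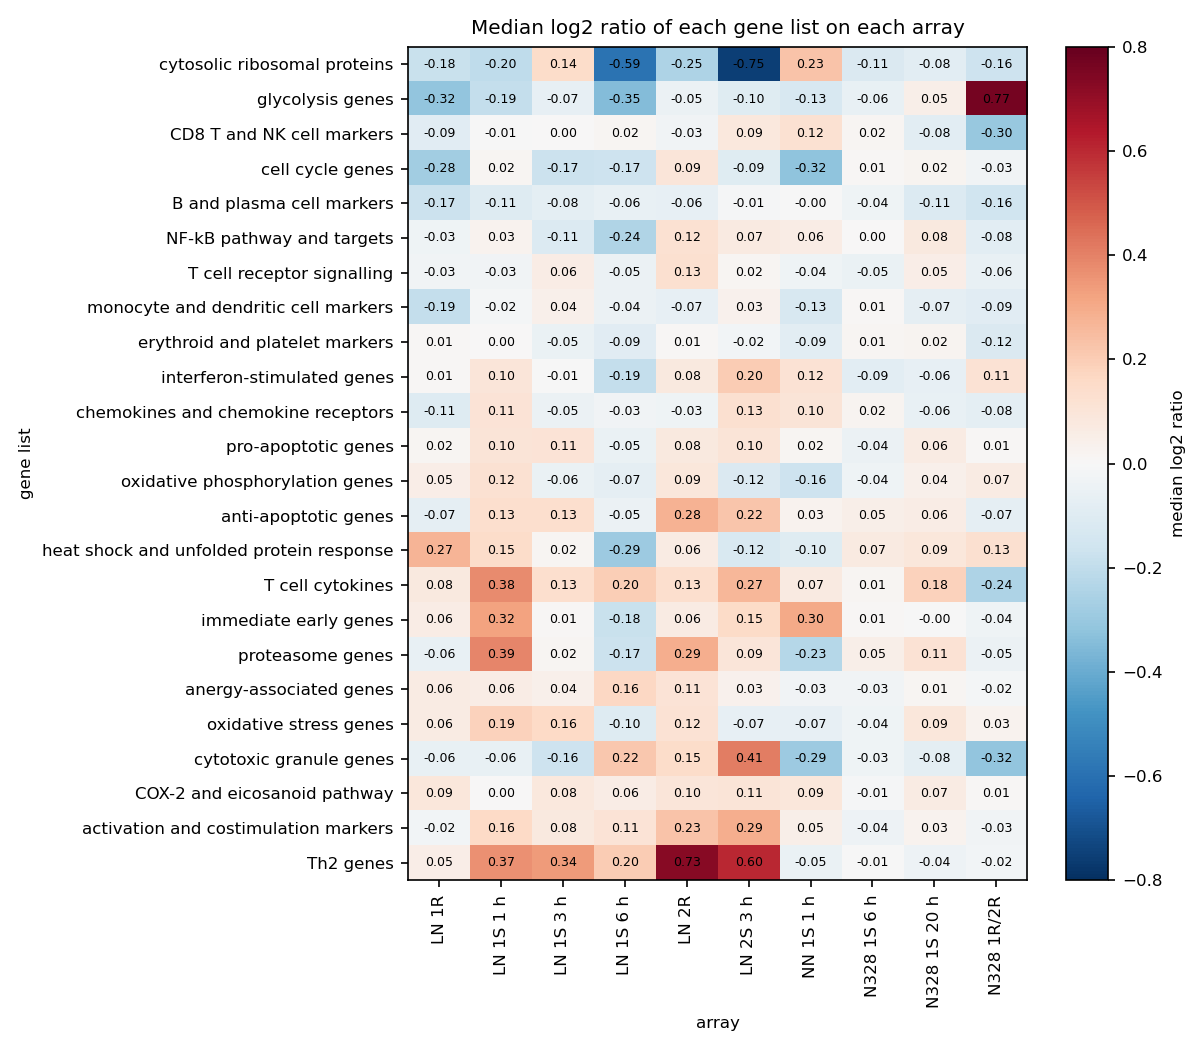
Median log2 ratio of each of the 24 tested gene lists (vertical axis) on each of the 10 arrays in annotation order (horizontal axis), with the value printed in each field and lists ordered from the lowest to the highest median in the mean of the LN arrays. The ribosomal protein list is at the top, from -0.75 to 0.14 on LN arrays, and the glycolysis list reaches 0.77 on the N328 array titled with both rests.

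Lists of cell death genes did not pass the test. Pro-apoptotic genes had 0 of 24 members called in either way (camera adjusted p = 0.501), with FAS at 0.13 ± 0.08 and its ligand FASLG at 0.00 ± 0.11. Anti-apoptotic genes (adjusted p = 0.46) had 1 of 19 called, and 2 higher and 1 lower when adjusted over the list alone. The inhibitor of apoptosis BIRC2 rose by 0.79 ± 0.07, while CFLAR (0.16 ± 0.07), BCL2 (0.28 ± 0.10) and BCL2L1 (0.28 ± 0.11) did not pass. In the COX-2 and eicosanoid list (adjusted p = 0.14) PTGS2 alone of 16 was called, and 4 were higher and 2 lower when adjusted over the list alone, HPGD, which degrades prostaglandins, standing at 0.95 ± 0.26 (adjusted p = 0.0924).

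T cell receptor signalling genes did not shift together (camera adjusted p = 0.669; median -0.02, mean 0.04), although NFATC3 (0.82 ± 0.10), LCP2 (0.61 ± 0.09) and CD3G (0.45 ± 0.08) rose and the kinase TXK fell (-0.64 ± 0.13). A total of 4 of 30 were called higher and 1 lower, 6 and 1 when adjusted over the list alone. CD247, the zeta chain of the receptor, stood at -0.16 ± 0.07 (adjusted p = 0.217) and FCER1G, which can take its place, at -0.21 ± 0.08 (adjusted p = 0.2). Interferon-stimulated genes (adjusted p = 0.501) had LY6E called of 36 (0.33 ± 0.07) and 0 when adjusted over the list alone, with ISG15 at 0.00 ± 0.07 and MX1 at 0.71 ± 0.30. Chemokines and their receptors (adjusted p = 0.705) had 3 higher and 2 lower of 23, 5 and 3 when adjusted over the list alone, with CCL1 at 1.20 ± 0.09 and CXCL13 at -0.46 ± 0.07 among them. Immediate early genes (adjusted p = 0.14) had 3 of 22 called with either adjustment, the growth-factor response genes JUN (0.68 ± 0.09), DUSP6 (0.92 ± 0.12) and EGR1 (0.38 ± 0.07). The NF-kB list (adjusted p = 0.833; median -0.03, mean 0.09) had CXCL8 alone of 22 called with either adjustment. Of these calls, LCP2, CD3G, TXK, LY6E and EGR1 ended without the LN array at 3 h (adjusted p 0.0516, 0.0725, 0.0934, 0.163 and 0.0792). LY6E and EGR1 also ended without 6 and 5 other arrays, each left out alone.

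Oxidative phosphorylation genes (44 members, adjusted p = 0.794), heat shock and unfolded protein response genes (23 members, adjusted p = 0.669; median 0.06, mean -0.03) and oxidative stress genes (14 members, adjusted p = 0.0973) had 0 members called over all genes, and 0, 1 lower and 0 when adjusted over the list alone. The fixed genes IL2 (-0.18 ± 0.51), IL10 (0.04 ± 0.08), CD69 (0.01 ± 0.07), EGR3 (0.12 ± 0.10), NR4A1 (0.08 ± 0.13) and TNFAIP3 (-0.15 ± 0.10) did not pass. IL2, the cytokine whose loss defines anergy, ranged from 2.32 at 1 h to -2.88 at 6 h of the first stimulation. Of the untested short lists, the Th1 members RUNX3 (0.23 ± 0.08), CXCR3, IL18R1 and HLX, and the regulatory T cell members TNFRSF9 (0.23 ± 0.07), LRRC32 (-0.20 ± 0.07), ENTPD1 and IL10, held 0 calls over all genes, and 0 and 3 (2 higher) when adjusted over the list alone.

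Markers of other cells were measured on the same arrays. CD8 T and NK cell markers (adjusted p = 0.794) had CD8A called of 7 (0.42 ± 0.09, adjusted p = 0.0429; 5 of 6 arrays), beside the granzymes that rose. CD8A was not called under 6 of 16 alternatives, and it stood at 0.17 without the second rest (adjusted p = 0.382). B and plasma cell markers (adjusted p = 0.0973) had MS4A1 called of 13 (-0.44 ± 0.07), and 4 lower when adjusted over the list alone. Monocyte and dendritic cell markers (adjusted p = 0.62) had ITGAX called of 19 (0.62 ± 0.08), also expressed by activated T cells, and erythroid and platelet markers (adjusted p = 0.817) had 0 of 10. The CD8 and monocyte lists held 1 call each with either adjustment and the erythroid list 0.

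These ratios keep any gene-specific dye effect, and the number of calls moved with the arrays and the scaling. It was 129 without the LN array at 3 h, 462 without that at 6 h, 158 without the second rest, 162 without the second stimulation and 174 without either N328 array, and 141 (95 higher, 46 lower) with MAD scaling, 84 (57 higher, 27 lower) with quantile normalization and 144 with arm means. All 141 and all 84 calls were among the 296. Without dim probes 330 were called, 217 of them among the 296. All probes of PTGS2, NRP1, NT5E, CBLB, TXK, CENPA and CD8A were among those left out, so that alternative could not test these genes. Of the 20 genes with the largest changes, 16 were called under every alternative that gave them a value. The exceptions were IL6ST (adjusted p = 0.0626 without the second rest), PCGF3 (0.152 without the 3 h array), FKBP5 (0.0515 and 0.0767 without the first rest and the 3 h array) and RPS29 (0.13 with quantile normalization). Of the 56 called genes that the rule named, list members included, 28 were called under every alternative that gave them a value. A further 22 lost the call when 1 array was left out. The anergy list was not called without the second rest, the cytotoxic list without the second rest or second stimulation, and the proteasome list without the 1 h array or the second rest, and none but the cytotoxic list of these 3 was called without dim probes, with highest adjusted p of 0.119, 0.185 and 0.355 over the alternatives at the preset correlation.

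The next comparison set the 6 LN arrays against the NN array, which the study included to account for variation between normal subjects. That array was at 1 h of the first stimulation, a time shared only by the LN array at 1 h. Differences between arms and between times could therefore not be separated. As an NN ratio has no set direction, each difference was also computed with the sign of that array turned. PTGS2 differed by 2.87 ± 0.42 (adjusted p = 0.0373, limma) and, turned, by 2.51 ± 0.42 (adjusted p = 0.0534), so its size owed little to that sign. NRP1 (2.59 ± 0.25, adjusted p = 0.0118), GZMH (1.80 ± 0.22), TBL1X (1.59 ± 0.24) and GZMB (1.54 ± 0.24) kept their direction but stood at 0.37, 0.83, 0.31 and 0.53 turned (adjusted p 0.766, 0.232, 0.784 and 0.561). Limma called 27 genes and probes, 17 higher and 10 lower, with 16 and 5 of them named genes and 648 at an unadjusted p under 0.05. Turned, it called 31, 9 higher and 22 lower, with 805 at an unadjusted p under 0.05. No gene or probe was called in the same direction both ways, and 19 of the 27 took the other direction. Without the LN array at 3 h 0 were called (PTGS2 at adjusted p = 0.105, NRP1 at 0.0604).

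Where a difference took the other direction, its larger part came from the single NN array, so its sign has no reading. Such differences were those of the interleukin receptor IL9R (3.56 ± 0.45, and -1.31 turned), GZMA (2.82 ± 0.40 and -1.36), CREM (1.88 ± 0.24 and -0.27), GDE1 (1.73 ± 0.26 and -0.08), LPXN (1.67 ± 0.25 and -0.60), HOXD9 (-1.51 ± 0.18 and 1.06), G0S2 (-1.47 ± 0.23 and 0.51), PDK1 (-1.42 ± 0.23 and 0.36) and the metallothionein MT1X (-1.23 ± 0.18 and 0.55), none of which passed when turned. Of these genes CREM (0.81), GZMA (0.73) and PDK1 (-0.53) were also called on the LN arrays against 0. RGS16, a brake on G protein signalling, passed both ways with opposite signs (-1.70 ± 0.17, and 2.47 turned, adjusted p = 0.00157). On the NN array IL9R stood at -2.43, GZMA at -2.09, RGS16 at 2.08 and HOXD9 at 1.29, whereas RGS16 lay between 0.01 and 0.54 on the 6 LN arrays. Of the remaining fixed genes none passed, and BCL2L1 (-0.51 ± 0.29), CBLB (-0.48 ± 0.18) and IL2 (-0.88 ± 1.34) had adjusted p of at least 0.489.

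Camera called 8 of 24 lists in this comparison, 6 up and 2 down, 9 with the NN array turned, and 0 with an estimated correlation. Th2 genes alone were called in 1 direction with either sign (median 0.37, adjusted p = 0.0108; turned 0.34, adjusted p = 0.047; adjusted p = 0.447 with an estimated correlation), with 0 members called over all genes and 2 higher when adjusted over the list alone. Ribosomal proteins lay lower (median -0.50 over 39 members, adjusted p = 6.19e-18; adjusted p = 0.564 with an estimated correlation) and at -0.07 turned (adjusted p = 0.678), with 0 members called in either way. The cell cycle list, which fell on the LN arrays against 0, had a median of 0.30 here (adjusted p = 2.98e-08; adjusted p = 0.432 with an estimated correlation) and -0.41 turned (adjusted p = 3.83e-13). The NN array stood at -0.32 for that list and the mean of the LN arrays at -0.08, so the positive difference came from the NN array alone. Cytotoxic granule genes had medians of 0.27 and, turned, 0.02 (adjusted p 0.00032 and 0.901; adjusted p = 0.432 with an estimated correlation). On the NN array they stood at -0.29. The median changed sign for proteasome genes (0.26 and -0.11; NN array -0.23), oxidative phosphorylation genes (0.13 and -0.14), heat shock genes (0.19 and -0.04) and immediate early genes (-0.15 and 0.42), called at adjusted p of 9.13e-05, 0.00958, 0.0246 and 0.00336. For these 4, adjusted p was 0.605, 0.605, 0.564 and 0.564 with an estimated correlation, and the heat shock list was not called without the first rest or the 3 h array (adjusted p 0.178 and 0.058). Over all genes 3 cytotoxic granule genes and 0 members of the 5 lists whose median changed sign were called. Adjusted over the list alone these were 4 cytotoxic granule genes, 8 cell cycle genes, 0 proteasome and oxidative phosphorylation genes, 3 heat shock genes, and 1 immediate early gene higher and 1 lower.

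No gene named in this comparison was called under every alternative, and PTGS2 was not called under 8 of 16 (highest adjusted p 0.79, limma, with arm means). PTGS2, NRP1 and HOXD9 had no value without dim probes. The count was 0 without the LN array at 3 h, 93 and 95 without those at 1 and 6 h, 12 without the second stimulation, 15 without either N328 array, 65 with MAD scaling, 50 with array weights, 12 (4 higher, 8 lower) with arm means, and 1, lower, with quantile normalization.

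Within the first stimulation, where anti-CD3 was given alone, 3 LN arrays (1, 3 and 6 h) were set against the NN array. As the latter was at 1 h, the hours matched only in part. Limma called 8 genes and probes, 4 in each direction, and 479 had an unadjusted p under 0.05. With the sign of the NN array turned it called 36, 10 higher and 26 lower, with 844 at an unadjusted p under 0.05, and again none in the same direction both ways. NRP1 stood at 2.80 ± 0.27 (adjusted p = 0.0138; positive on 3 of 3 arrays) and 0.58 turned (adjusted p = 0.531). GZMH stood at 1.81 ± 0.23 (adjusted p = 0.0351) and 0.85 turned (adjusted p = 0.247). The other 3 named calls, at adjusted p = 0.0351 each, took the other direction when turned: the actin regulator ENAH (1.77 ± 0.22 and -0.94), HOXD9 (-1.52 ± 0.20 and 1.05) and RGS16 (-1.60 ± 0.19 and 2.57, adjusted p = 0.002). All 5 calls ended without the LN array at 3 h (adjusted p 0.0793, 0.0905, 0.114, 0.17 and 0.114 in this order). Below the threshold were PTGS2 (3.01 ± 0.45, adjusted p = 0.0679; turned 2.65, adjusted p = 0.0522), GZMB (1.72 ± 0.26, adjusted p = 0.0679; turned 0.71) and the chaperone HSPA1A (2.82 ± 0.41, adjusted p = 0.0633; turned -2.97, adjusted p = 0.0223). So were PDK1 (-1.52 ± 0.24, adjusted p = 0.0734), MT1X (-1.08 ± 0.19) and MED13L (-1.25 ± 0.23), the last 3 at 0.25, 0.71 and 0.74 turned.

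Camera called 7 lists here, 3 up and 4 down, and 5 turned, with none in the same direction both ways. The medians of these 7 with the NN array as deposited and turned were 0.25 and -0.43 for cell cycle genes, -0.46 and 0.04 for ribosomal proteins, -0.28 and 0.43 for immediate early genes, 0.21 and -0.16 for proteasome genes, 0.20 and -0.16 for cytotoxic granule genes, -0.20 and 0.06 for interferon-stimulated genes, and -0.15 and -0.05 for NF-kB genes. In this order, adjusted p was 5.36e-08, 6.43e-13, 0.000366, 0.00117, 0.011, 0.0115 and 0.0217. Likewise, adjusted p was 0.579, 0.615, 0.579, 0.719, 0.579, 0.698 and 0.615 with an estimated correlation. The cell cycle medians of the 3 LN arrays were 0.02, -0.17 and -0.17, so no rise of cell cycle genes on LN arrays lay behind the first difference. Adjusted over the list alone, 1 immediate early gene was lower and 5 cell cycle genes and 4 cytotoxic granule genes were higher, against 0, 0 and 1 over all genes, and the other 4 lists had 0 members called in either way. Leaving out the 6 h array ended the calls of the interferon, cytotoxic and NF-kB lists (adjusted p 0.213, 0.0652 and 0.218), and leaving out the 1 h array ended that of the proteasome list (0.333).

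The count of genes was 0 without the LN array at 3 h, 33 and 15 without those at 1 and 6 h, 2 without either N328 array, 19 (11 higher, 8 lower) with MAD scaling, 0 with quantile normalization and 4 (3 higher, 1 lower) without dim probes. Against 0 instead of the NN array, the 3 LN arrays gave 40 calls, 28 higher and 12 lower. That count was 10 without the 3 h array, 22 without either N328 array, 6 with MAD scaling, 10 with quantile normalization and 70 without dim probes.

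Anti-CD3 alone was compared with anti-CD3 and anti-CD28 through the N328 arrays at 6 and 20 h, set against the NN array at 1 h. The sides share no time point, so a difference between arms cannot be told apart from one between hours. Limma called 2 genes and probes, both lower, of which 1 was a named gene, RGS16 (-1.83 ± 0.20, adjusted p = 0.0293), and 366 had an unadjusted p under 0.05. With the NN array turned it called 2 again, both higher, RGS16 among them (2.34, adjusted p = 0.00733), with 440 at an unadjusted p under 0.05. The size of the RGS16 value therefore rested on the NN array, and its sign has no reading. The genes with the smallest p on the higher side, all below the threshold, were the kinetochore genes CENPE (1.91 ± 0.27) and CENPF (1.36 ± 0.21), the histone H2AX (1.37 ± 0.20), HSPA1A (2.91 ± 0.43) and LIMA1 (1.49 ± 0.23), with adjusted p of 0.115 to 0.125. All 5 were negative when turned (-1.29, -1.15, -1.54, -2.88 and -0.99). On the lower side they were HOXD9 (-1.50 ± 0.21; turned 1.08), APBA3 (-1.24 ± 0.23), CTRB1 (-1.08 ± 0.22) and F2 (-1.07 ± 0.22), with adjusted p of 0.115 to 0.264. PTGS2 stood at 0.82 ± 0.48, IL2 at -0.33 ± 1.52 and GZMB at 0.32 ± 0.27, and none of the fixed genes passed.

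RGS16 itself stood at 0.18 and 0.33 on the N328 arrays and at 2.08 on the NN array. Tested against 0, the N328 ratios gave 0 calls (limma; 90 at an unadjusted p under 0.05), and 2 without the N328 array at 6 h. The RGS16 call ended without the LN array at 3 h, without either N328 array and with quantile normalization (adjusted p 0.0978 to 0.363), and the count of calls rose to 12 without the LN array at 6 h, 12 (7 higher, 5 lower) with MAD scaling, 7 (3 higher, 4 lower) with array weights and 4 (1 higher, 3 lower) with arm means. It was 1 without dim probes.

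By list, camera called 8 in this comparison, 4 up and 4 down, and 4 turned, with none in the same direction both ways. Cell cycle genes had the smallest p (median 0.37 over 53 members, adjusted p = 2.14e-15; adjusted p = 0.323 with an estimated correlation; 0 called over all genes and 15 when adjusted over the list alone), and a median of -0.37 turned (adjusted p = 1.22e-09). Their medians were 0.01 and 0.02 on the N328 arrays and -0.32 on the NN array, so the difference was that of the NN array. The other medians, as deposited and turned, were 0.29 and -0.17 for proteasome genes, 0.15 and 0.00 for heat shock genes, 0.14 and -0.16 for oxidative phosphorylation genes, -0.34 and 0.13 for ribosomal proteins, -0.31 and 0.26 for immediate early genes, -0.20 and 0.02 for interferon-stimulated genes, and -0.12 and 0.10 for chemokines and their receptors. In this order adjusted p was 0.000664, 0.00553, 0.0221, 3.85e-10, 4.46e-06, 0.000512 and 0.00426. Likewise, adjusted p was 0.688, 0.617, 0.688, 0.617, 0.519, 0.617 and 0.519 with an estimated correlation. Adjusted over the list alone, 3 heat shock genes were higher and 1 immediate early gene and 1 chemokine gene lower, against 0 over all genes. Without the N328 array at 20 h, 4 lists were called, and the chemokine, oxidative phosphorylation, proteasome and heat shock lists were not (adjusted p 0.0505, 0.291, 0.0517 and 0.07). Against 0, 1 list was called.

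Whether the lupus/normal profile resembled that of missing costimulation was described across genes, which are not independent replicates. The mean of the 3 LN arrays and the mean of the 2 N328 arrays of the first stimulation, which share no array, correlated with Pearson's r = 0.29 and Spearman's rho = 0.31. The LN mean correlated with the NN array at r = 0.17 and the N328 mean at r = 0.09. Single LN and N328 arrays correlated at -0.21 to 0.37, and without the N328 array at 20 h the r of the means was -0.01. With the NN array taken off both, r was 0.757, against 0.707 in simulations where only that shared array linked the profiles. It was 0.822 with that array turned, and the covariance was 0.0655 against a simulated 0.0439. The simulated array had only the residual spread of the fit, while the real NN array carried its own ratios as well (SD 0.27 over its rows). The simulations therefore cannot show a link beyond the shared array. As there was 1 NN array, it could not be split.

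A contrast added after the data had been seen set the 4 stimulated LN arrays against the 2 at rest. Its values are changes of the lupus/normal ratio, since no LN array compared stimulated with resting cells. The lupus/normal ratio of the chemokine CCL1 was higher on the stimulated arrays by 2.03 ± 0.19 (adjusted p = 0.0143, limma; positive on 4 of 4 stimulated arrays, at 1.58 to 2.18, and at -0.24 and -0.05 at rest). CCL1 was the only call, with 512 genes and probes at an unadjusted p under 0.05. Next by p, and below the threshold, were MYB (1.34 ± 0.18), PTGS2 (2.26 ± 0.34), CCR7 (1.34 ± 0.21) and KLRC3 (0.94 ± 0.16) on the higher side, and the cytokine IL32 (-1.66 ± 0.20, adjusted p = 0.0631), the chaperones HYOU1 (-0.88 ± 0.14) and PPIB (-0.92 ± 0.15), CDADC1 (-0.85 ± 0.14) and RPS6KA5 (-1.18 ± 0.20) on the lower, with adjusted p of 0.131 to 0.165 for those other than IL32. No fixed gene passed, and those other than PTGS2, such as GZMB (0.93 ± 0.19), CD69 (-0.73 ± 0.15) and FAS (-0.69 ± 0.16), had adjusted p of at least 0.302.

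The lupus/normal ratios of chemokines and their receptors were higher as a list on the stimulated arrays (camera adjusted p = 0.000638; 1 of 23 called, 3 when adjusted over the list alone). Those of oxidative phosphorylation genes (adjusted p = 0.000251; 0 of 44 with either adjustment) and heat shock and unfolded protein response genes (adjusted p = 0.000911; 0 of 23, and 6 lower when adjusted over the list alone) were lower. All 3 had adjusted p = 0.903 with an estimated correlation, and the heat shock list was not called without the first rest or the 6 h array (highest adjusted p 0.464). The number of lists called was 6, 7, 5 and 8 without the first rest, the 1 h array, the 3 h array and the second rest. The CCL1 call ended without the LN array at 3 h (adjusted p = 0.106) or without either N328 array (adjusted p = 0.0504), over a range of 0.00317 to 0.106, and the count of calls was 7, 3, 11, 4 and 2 without the first rest, the 1 h array, the 6 h array, the second rest and the second stimulation. It was 3 (2 higher, 1 lower) without centring and 2 (1 higher, 1 lower) with MAD scaling, robust eBayes, array weights or no dim probes.

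Another added contrast set the 6 LN arrays against the 3 arrays without lupus cells. The latter were all from the first stimulation (1, 6 and 20 h), so the sides also differed in stage. No gene was called by limma (406 at an unadjusted p under 0.05), the smallest adjusted p being 0.083 for the motor protein MYO1E (1.01 ± 0.14) and 0.0987 for NRP1 (1.80 ± 0.27). TBL1X (1.11 ± 0.19), LIF (1.06 ± 0.19) and SLC6A6 (0.65 ± 0.13) followed, with PRPF8 (-0.50 ± 0.10), IL7R (-1.52 ± 0.31), NELL2 (-1.04 ± 0.22), PATJ (-0.82 ± 0.18) and ABLIM1 (-0.89 ± 0.20) on the lower side. The first 5 of these genes were positive on 6 of 6 LN arrays and the other 5 on 0 of 6, with adjusted p of up to 0.61. Of the fixed genes, PTGS2 stood at 2.33 ± 0.83 (adjusted p = 0.945; turned 2.21, adjusted p = 0.854) and GZMB at 1.33 ± 0.35 (adjusted p = 0.653; turned 0.99, adjusted p = 0.854), and none passed. With the NN array turned 0 were called (480 at an unadjusted p under 0.05). Adjusted p was then 0.0522 for MYO1E (1.07) and 0.68 for NRP1 (1.06). The count was 4 without the first rest, 3 without the N328 array at 6 h and 1, higher, with array weights.

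Camera called 9 lists in that contrast, 7 up and 2 down, again with 0 held with an estimated correlation. Ribosomal proteins (adjusted p = 1.37e-12) and glycolysis genes (0.0402) lay lower. Activation markers, proteasome and Th2 genes (0.00606 each), cytotoxic granule genes (0.0121), anergy-associated genes (0.0402), T cell cytokines and oxidative stress genes (0.0499 each) lay higher. For proteasome genes adjusted p = 0.802 with an estimated correlation, with 0.479 for cytotoxic granule genes and 0.448 for the other 7. With the NN array turned 8 lists were called, among them 5 of the 9 in the same direction (ribosomal proteins, glycolysis, Th2 and activation genes and cytokines; adjusted p 0.00489, 0.00106, 0.00489, 0.000821 and 0.00225). Proteasome genes (0.978), cytotoxic granule genes (0.379), oxidative stress genes (0.241) and anergy-associated genes (0.0528) were not. Only the ribosomal list was called under every other alternative, and the number of lists was 4 without the 1 h array or the second rest, 5 without the N328 array at 6 h, 4 with quantile normalization and 5 with single probes or array weights. No member was called over all genes, and 2 anergy-associated genes, 2 cytokines, 3 cytotoxic granule genes and 2 Th2 genes were higher when adjusted over the list alone.

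The N328 array titled with both rests had no replicate, so its values carry no error and no test, and they are likely first over second rest from the order of its title. Arginase ARG2 stood at 3.44, the ectonucleotidase ENTPD1 at 2.44, the interferon-induced IFI44L at 2.21, LIMA1 at 1.80, MAOA at 1.77 and the glycolytic enzyme PGK1 at 1.57. GAB2, PTPN14, ZNF395 and FAM107B stood between 1.52 and 1.56. The lowest values were those of LTB, which organizes lymphoid tissue (-2.56), the receptor KLRB1 (-2.36), TGFBR1 (-1.74), the survival gene BCL2 (-1.70), FKBP5 (-1.63), DDX5 (-1.63), LST1 (-1.46), CTSH (-1.40), NELL2 (-1.28) and TPT1 (-1.24). In spot brightness NELL2 lay at percentile 3.57 of all genes and probes, TGFBR1 at 14.6 and ZNF395 at 20.9. The other genes listed so far for this array lay at 30.8 to 99.3. BCL2L1 stood at a ratio of -1.04 and GZMB at -1.15. The glycolysis list had a median of 0.77, above all 10000 random lists matched on brightness, with 12 of 15 members positive, among them ALDOA at 1.43, PGAM1 at 1.18 and LDHA at 0.80.

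**Figure D4:**
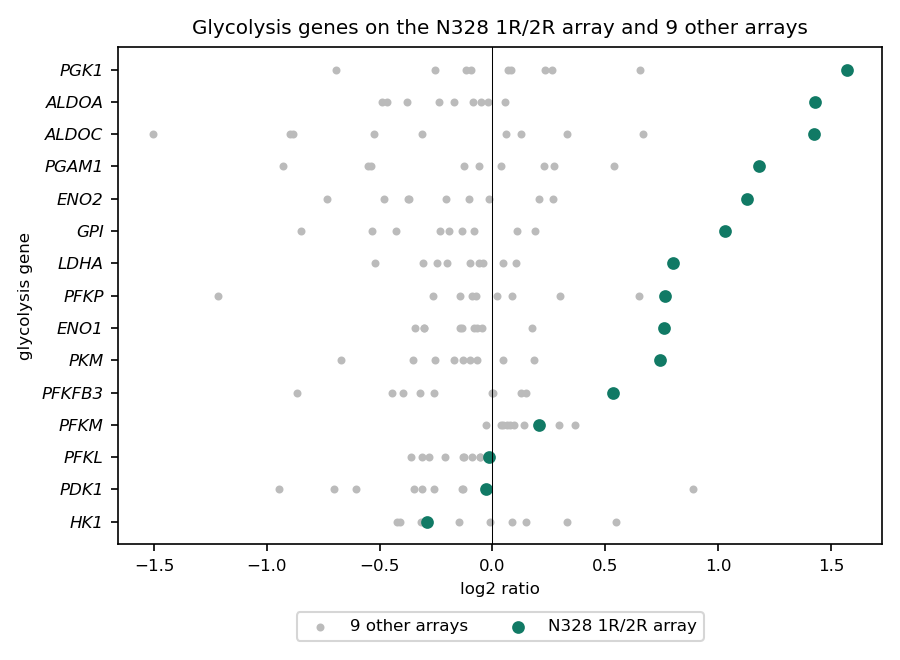
Log2 ratio (horizontal axis) of the 15 measured glycolysis genes (vertical axis) on the N328 array titled with both rests (green) and on the 9 other arrays in annotation order (grey). PGK1 has the highest green value, 1.57, and HK1 the lowest, -0.29.

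Comparisons of LN or N328 with NN arrays in the second stimulation and at rest, the change between the 2 stimulations and the time trend were not possible on genes, because those NN arrays were not in annotation order. A contrast of second against first stimulation on LN arrays, with 1 array against 3, gave 0 calls (limma; 505 at an unadjusted p under 0.05), and 5 and 3 without the LN arrays at 1 and 6 h. The 2 LN arrays at rest against 0 gave 77 calls, 57 higher and 20 lower. That count was 7 without the second rest, 116 without the first, 129, 21 and 180 without the arrays at 1, 3 and 6 h, 38 without either N328 array and 1 with quantile normalization.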

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

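In this part, the tests of a shared dye or spot effect on ribosomal and glycolysis genes, and the contrast of stimulated against resting LN arrays, were chosen only after the results were seen. Of 51 groups of values tested for an array far from the others, 5 had one, where chance gives about 1 in 20 groups.

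The LN array at 20 h of the first stimulation held 8469 values, against 9128 to 9182 on the others of its group. The NN array at 3 h of the first stimulation held 747 values of exactly 0, against 35 to 83. The N328 array at 3 h held 6963 values, against 8817 to 9182. FASLG, the ligand of the death receptor FAS, stood at -0.67 on the LN array at 6 h, against 0.04 to 0.25 on the other 5 LN arrays. CBLB stood at 0.0932 on the LN array at the second rest, against -0.53 to -0.30 on the other 5.

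The lupus/normal ratio differed between stimulated and resting LN arrays for CCL1 (2.03, limma). By limma's camera it also differed for chemokines and their receptors (median 0.11), oxidative phosphorylation genes (-0.11) and heat shock and unfolded protein response genes (-0.14). All 3 lists had adjusted p = 0.903 with an estimated correlation in limma's camera, and the CCL1 call ended without the LN array at 3 h (adjusted p = 0.106, limma) or either N328 array (adjusted p = 0.0504). The 7 arrays in the other shared row order, which could not be tied to genes, held 10 rows called in the 4 NN arrays against 0 (8 higher, 2 lower) and 10 in LN against NN (6 higher, 4 lower), each of 9128 rows tested with limma. The latter set 1 LN array against 4 NN arrays and took its spread from the NN and N328 arrays. The 2 N328 arrays of this order gave 0 calls against NN and 0 against 0 (limma; 116 and 379 at an unadjusted p under 0.05).

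The first pattern weighed was the set of 296 genes and probes called on the LN arrays, and the first technical explanation was a dye or spot effect shared by all arrays. On the 3 arrays without lupus cells used in the tests, the called genes kept at most 28.6% of their LN median in size, below the 50% set in advance, and on the N328 array titled with both rests 17.1%, although 234 of the 296 had the LN sign on the N328 array at 20 h, 184 on that at 6 h and 137 on the NN array. As the genes were chosen by their LN values, smaller values elsewhere follow in part from that choice, so these shares cannot exclude a dye or spot effect. The second was noise of dim spots, and 27.7% of the calls (exact 95% interval 22.7% to 33.2%) lay among the dimmest 25% of genes. The third was random signs, and 1 of 32 sign patterns of the 6 arrays called as many genes, the real one, the next highest calling 79. As the real pattern always counts, 1 is the lowest number possible. The outcome needs only LN arrays that resemble each other, which a shared dye effect would also give. By the rules set in advance none of the 3 explained the whole pattern, although the first rule could not exclude its effect. Over all probes LN arrays correlated with N328 arrays (median rho 0.22) as much as with each other (0.18), and arrays of different arms as much as arrays of 1 arm (0.16 and 0.16; 0.34 and 0.25 in the other shared order), so a part shared by all arms stays open beside a difference between lupus and normal cells.

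The second pattern was the fall of ribosomal protein genes, called by limma's camera at the preset correlation and with adjusted p = 0.462 with an estimated correlation. Their median lay at percentile 0 of random lists matched on spot brightness in 20 bins, so differences in brightness between bins did not account for it. Bias within a bin was not tested, and the random lists leave out correlation between ribosomal genes. A dye or spot effect shared by all arrays stayed open, since the median on the 4 arrays without lupus cells reached 26.9%, 37% and 53.2% of the LN value in size on the N328 arrays and 73.2% on the NN array, whose sign has no meaning, neither all under 50% nor all over 75%. An earlier form of this test, on 3 of these arrays with signs kept, had set the effect aside at 37%, and was changed after its values were seen. No test separated a difference between lupus and normal cells from one between single cultures.

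The third pattern was the glycolysis list on the N328 array titled with both rests. Its median lay at percentile 100 of random lists matched on brightness, so random lists of like brightness did not reach it. The list had been singled out by this same value, so the percentile cannot exclude bias that depends on brightness. On the 9 other arrays the median reached at most 45.1% of that value in size. As the list was singled out by its value on this array, smaller values elsewhere follow in part from that choice. This share therefore cannot exclude a shared dye effect. A technical fault of this array alone was not tested. With 1 array, a biological difference between the rests could not be tested.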

How the results depend on the processing

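The fit to all 26 arrays, the fit without dim probes, the turned sign of the NN array, and every alternative for the added contrasts were chosen only after the results were seen; the other alternatives were planned. Genes called in LN against 0 (296) were 141 with MAD scaling, 84 with quantile normalization and 144 with arm means. Without dim probes they were 330, of which 217 were among the 296. LN against NN over all times (27) gave 65 with MAD scaling, 1 with quantile normalization, 50 with array weights, 12 with arm means, 296 against 0 and 16 over 26 arrays. In the first stimulation, LN against NN (8) gave 19, 0, 4 and 36 with MAD scaling, quantile normalization, no dim probes and the NN array turned, 40 against 0 and 0 over 26 arrays. N328 against NN (2) gave 12, 0, 7, 4 and 1 with MAD scaling, quantile normalization, array weights, arm means and no dim probes, 0 against 0 and 0 over 26 arrays. Stimulated against resting LN arrays (1) gave 3 without centring and 2 with MAD scaling, robust eBayes, array weights or no dim probes, and LN against arrays without lupus cells (0) gave 1 with array weights. NN against 0 (13) gave 51 with MAD scaling, 2 with quantile normalization, 24 with array weights, 8 with arm means, 7 without dim probes, 0 over 26 arrays and 0 to 51 when 1 array was left out. With an estimated correlation, camera called 0 lists in each of the 6 contrasts. N328 against 0 gave 1 list and N328 against NN 4 with the NN array turned, and LN against arrays without lupus cells gave 4 lists with quantile normalization, 5 with single probes and 5 with array weights. The profile correlation was 0.757 with the NN array taken off both, and 0.822 with it turned, where sharing that array raises it by construction. Turning the NN array reversed 15 differences of named genes that passed with at least 1 of the signs. In LN against NN over all times IL9R came to -1.31, GZMA to -1.36, CREM to -0.27, GDE1 to -0.0825, LPXN to -0.60, RGS16 to 2.47, HOXD9 to 1.06, G0S2 to 0.51, PDK1 to 0.36 and MT1X to 0.55. In the first stimulation ENAH came to -0.94, HSPA1A to -2.97, RGS16 to 2.57 and HOXD9 to 1.05. In N328 against NN RGS16 came to 2.34. Turning that array also reversed the direction that limma's camera gave to lists called with at least 1 of the signs (unadjusted p, turned). In LN against NN over all times they were interferon-stimulated (0.00843), cytotoxic (0.901), immediate early (5.54e-07), cell cycle (1.6e-14), oxidative phosphorylation (0.0147), proteasome (0.219) and heat shock genes (0.152). In the first stimulation they were interferon-stimulated (0.148), cytotoxic (0.288), immediate early (8.73e-05), NF-kB (0.613), cell cycle (1.09e-12), oxidative phosphorylation (0.00781), ribosomal (0.43) and proteasome genes (0.0993). In N328 against NN they were chemokine (0.0783), interferon-stimulated (0.281), cytotoxic (0.00243), immediate early (2.51e-05), cell cycle (5.09e-11), oxidative phosphorylation (0.00302), ribosomal (0.0207), proteasome (0.0471) and heat shock genes (0.201). In LN against arrays without lupus cells they were immediate early (0.000113) and cell cycle genes (2.48e-09). The direction in camera can differ from that of the median. The median kept its sign for cytotoxic genes in LN against NN over all times (0.27 and, turned, 0.02). It also did so for NF-kB genes in the first stimulation (-0.15 and -0.05) and heat shock genes in N328 against NN (0.15 and 0.004). Leaving out 1 array at a time gave 129 to 462, 0 to 95, 0 to 33, 0 to 12, 0 to 11 and 0 to 4 genes in the 6 contrasts in the order above, 6 to 12, 7 to 11, 6 to 9, 4 to 10, 2 to 8 and 4 to 10 lists, and a profile correlation of -0.0129 to 0.387. A list that had not been called turned its direction in limma's camera in 3 cases: without the second rest, cytotoxic granule genes (unadjusted p = 0.0131, range when each array was left out 0.000534 to 0.85) and cell cycle genes (unadjusted p = 0.000174, range 1.82e-05 to 0.814) in stimulated against resting LN arrays, and without the NN array, cell cycle genes (unadjusted p = 5.88e-05, the lowest of a range up to 0.77) in LN against arrays without lupus cells. The sign of the NN array is arbitrary, so what moved with it has no set direction. Apart from that, smaller numbers of arrays, and the spread that the N328 arrays lend to contrasts without them, the cause was not tested. No paired analysis was possible because replicate numbers in the labels only stand for time points, and the 9 arrays used share too few time points between arms. Filters on missing values were not run, since the arrays used had none, and a block for time, the trend over hours and the planned comparisons at rest, in the second stimulation and between stimulations gave no value on genes. Scanner signals over background were not used here, so what signal depth limits was not measured.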

Other observations

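In this part, the regroupings of arrays, the test of effector memory genes and the spread required of both memory lists were chosen only after the results were seen.

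On the NN array at 1 h, which set lines of normal subjects against each other, the highest values after CXCL8 and RGS16 were those of TRIB1 (1.96), DUSP2 (1.52), SDC4 (1.51), TNF (1.51) and WARS1 (1.40). The lowest were those of the chaperones HSPA1A (-2.90) and HSPH1 (-1.94), and of IL9R (-2.43), SLC26A3 (-2.39), GZMA (-2.09) and ANXA1 (-1.86). The direction of these values has no biological meaning, and of these genes only RGS16 and HSPA1A passed limma's test of the array against 0, which takes its spread from the other groups.

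A hypothesis formed here was that the lower CCR7, IL7R and NELL2 and the higher GZMB and GZMH on LN arrays reflect lupus lines with fewer naive or central memory cells and more effector memory cells. NELL2 lay at percentile 3.57 of all genes and probes in spot brightness, so its ratio rests on dim spots. Of 32 further naive and central memory genes, 12 were measured and not named before, and their median of -0.05 lay at percentile 3.94 of brightness-matched random lists, where 2.5 had been set as the limit. Of 28 effector memory genes, 18 were measured and not named before, and their median of 0.16 lay at percentile 100, with LGALS1 (0.41), LGALS3 (0.33), ID2 (0.38) and ITGA4 (0.63) called by limma. By the limits first set, the first list missed and the second passed. After these values were seen, the rule was changed to require that resampling the members leave the percentile past the limit, and as it then ran from 0 to 66.6 and from 0.46 to 100, the result for both lists was that the data cannot tell. The effector list was written after ITGA4 had been seen among the results, so it is not an independent test.

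Regrouping the 9 arrays into 6 and 3 could not test the contrast of LN with the arrays without lupus cells. The real grouping called 0 genes with limma (406 at an unadjusted p under 0.05), so all 84 of 84 groupings reached that count whatever the data held, and the regrouping decided nothing. The highest count of another grouping was 21.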
